A study of Rattus norvegicus with 6 samples.

How the data were processed

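MicroRNAs of the left ventricle were measured by RT-qPCR in 3 OLETF rats, an inbred strain that develops obesity and type 2 diabetes, and 3 LETO rats, the non-diabetic strain used as its control. Per the labels' protocols, RNA was extracted with a small RNA kit, reverse-transcribed with pooled stem-loop primers and amplified on TaqMan rodent miRNA cards in a 7900HT instrument, with U6 snRNA as the endogenous control. Groups and replicate numbers were taken from the sample labels. The labels name 1 heart tissue sample per replicate and do not say that the rats came from separate litters or days. No p-value here therefore speaks for more than these 6 samples.

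The first deposited table held the threshold cycle (Ct) of each well, per the file headers and the labels, with wells that did not amplify marked as undetermined. A Ct is a number of PCR cycles, so a lower Ct means more RNA, and 1 cycle is 1 log2 unit if each cycle doubles the product. Each sample had 768 wells in 2 blocks of 384 rows, called card A and card B here. The deposited normalized values were delta Ct, a log2 quantity with the sign reversed, and the authors' formula was recomputed from the Ct table. It was Ct minus the mean of the 4 U6 wells of the same block. Several wells of an assay on card B entered as the mean of their determined wells. An assay with no determined well was counted as 40. Recomputed and deposited values differed by at most 3.75e-06 over 3570 values. The third deposited table held a linear ratio (fold) of OLETF over LETO per well. On card A, all 380 ratios of wells other than U6 equalled 2 raised to minus the difference of the group means of delta Ct, within 0.001 on the log2 scale. On card B, with each well taken by itself and undetermined wells counted as 40, this held for 194 of 380 wells. All 64 choices of which samples enter as the mean of the determined wells of an assay were then tried, after seeing the data. The ratios of 380 of 380 wells were obtained when replicate 3 of each group entered as that mean and the other 4 samples entered well by well, while the next best choice gave 287. The reason for this difference is not given in the sources used here, nor are the baseline and threshold settings of the instrument. Because it sets replicate 3 of each group apart from replicates 1 and 2, it was added as a batch to the alternatives.

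From the Ct table, the determined wells of an assay were averaged, and a mean Ct of 35 or more, or no determined well, was treated as not measured. The level of a miRNA was minus the difference between its Ct and the U6 Ct of the same card, on the log2 scale. Of 584 miRNA assays, 193 were measured in at least 2 of 3 samples of each group and were tested. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. With U6, limma in effect pooled the SE over assays. Both let-7b (SD 1.15 in LETO and 0.273 in OLETF) and miR-9 (SD 2.32 and 1.87) had an SE of 1.38. Such an SE is not the spread of a single miRNA. As whole samples shifted together, pooling over assays adds no replicates. Single values were compared with two-sided exact permutation tests, for which 3 against 3 samples allow no p below 0.1. Precision was judged from assays with 2 wells on card B: over 189 pairs of measured wells, the SD of a single well was 0.485 cycles.

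Before the data were examined, the U6 reference, the Ct limit, the filter, the tests, 17 miRNA lists and the rule for named miRNAs were fixed. The lists were the muscle miRNAs (myomiRs), fibrosis, the miR-30, let-7, miR-15/16 and miR-130/miR-301 families, miR-17-92 with its paralogues, the miR-23/24/27 clusters, glucose metabolism, the Dlk1-Dio3 imprinted cluster, and markers of endothelium, smooth muscle, erythroid cells, leukocytes, brain, liver, and epithelium and islet. Lists with at least 3 members measured in all 6 samples, 11 of the 17, were tested with camera in limma at a preset correlation of 0.01. The rule named up to 10 miRNAs per direction at adjusted p under 0.05. It filled a direction up to 8 with miRNAs that moved alike in all 9 pairs of OLETF and LETO samples. It always named miR-301b, miR-301a, miR-130a and miR-130b. As miR-301b was chosen from published work on these rats, that choice is not known to be independent of these data. The rule also named from each list the 2 members with the highest level and the 2 with the smallest p. It added up to 5 assays per direction measured in 1 group only, and every control. Its first 2 parts named 0 miRNAs with the U6 reference. The 12 miRNAs named for separating the groups under 2 median references were chosen after their values were seen.

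The alternatives fixed at that point were other references (the whole-array median, other small RNA controls, quantile normalization, U6 pooled over both cards), the deposited normalized table, Ct limits of 32, 38 or none, missing values set to the limit, assays measured in all 6 samples, trended robust eBayes, an ordinary equal-variance test per assay, the replicate number as a block, array weights, an estimated correlation for the lists, and each sample left out in turn. The median of each card as reference, the batch of replicate 3, and an agreement with the deposited ratios over card A alone were added after seeing the data. The fit was tested on simulated data for the comparison of 3 OLETF with 3 LETO samples over 193 assays. In each simulation 40 assays were changed, and a call of a changed assay counted whatever its direction. The first setting shifted whole samples as the levels relative to U6 were shifted here (SD 1.51). There the fit called 6.43%, 11.8% and 21.8% of changes of 1, 2 and 3 log2 units. The mean was 8.76 false calls among the unchanged assays. The share called at 1 log2 unit was thus close to the rate of calls without any change. The second setting had no shift of whole samples, as an ideal median reference would leave, and independent noise of SD 0.745. There the fit called 12.3%, 62.8% and 96.6%. The mean was then 0.92 false calls. No median was taken in that setting, and it held no gap between cards and no other structure of the samples. It is therefore no estimate for the median references used here. Assay names are those of the card design. No genome build is stated for these files, so no coordinates are given.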

Results

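Levels of 584 miRNA assays were measured in the left ventricle of 3 diabetic OLETF rats and 3 non-diabetic LETO rats. The question was which cardiac miRNAs differ between them. All diabetic rats were OLETF and all others LETO, so a difference cannot be assigned to diabetes apart from strain and obesity. Marker miRNAs of heart muscle and vessels were measured in all samples. Relative to U6, miR-133a, a muscle miRNA, lay at 0.89 ± 0.77 log2 units in LETO and 0.46 ± 0.40 in OLETF (SD, n = 3 each), and miR-126-3p, an endothelial miRNA, at -1.42 ± 1.26 and -1.48 ± 0.95. Of all assays, 162 were measured in all 6 samples, 275 in none and 147 in 1 to 5 samples. The number measured was 207, 202 and 292 in LETO replicates 1, 2 and 3, and 197, 200 and 228 in the OLETF replicates (234 ± 50.6 against 208 ± 17.1; exact permutation p = 0.5). LETO replicate 3 alone measured 50 assays that no other sample did, and without it the difference of -25.3 assays turned to 3.83.

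The U6 reference did not separate the groups. Its Ct on card A was 18.2 ± 0.908 in LETO and 17.9 ± 0.290 in OLETF (difference -0.25, exact permutation p = 0.9, n = 3 each), and on card B 17.3 ± 1.03 and 17.2 ± 0.549 (difference -0.022, exact permutation p = 1). The other small RNA controls snoRNA135, U87 and Y1 did not separate the groups either. On card A, snoRNA135 lay at a Ct of 29.6 ± 2.19 in LETO and 30.2 ± 1.11 in OLETF, U87 at 26.1 ± 1.82 and 26.1 ± 0.578, and Y1 at 29.1 ± 3.94 and 30.3 ± 2.33 (exact permutation p = 0.8, 1 and 0.7). On card B, snoRNA135 differed by 1.79 cycles and U87 by 1.18 cycles (exact permutation p = 0.4 and 0.3). Y1 on card B was measured in 5 of 6 samples, snoRNA202 in 2 samples on card A and 0 on card B, and the plant control ath-miR159a and snoRNA429 in 0.

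**Figure D1:**
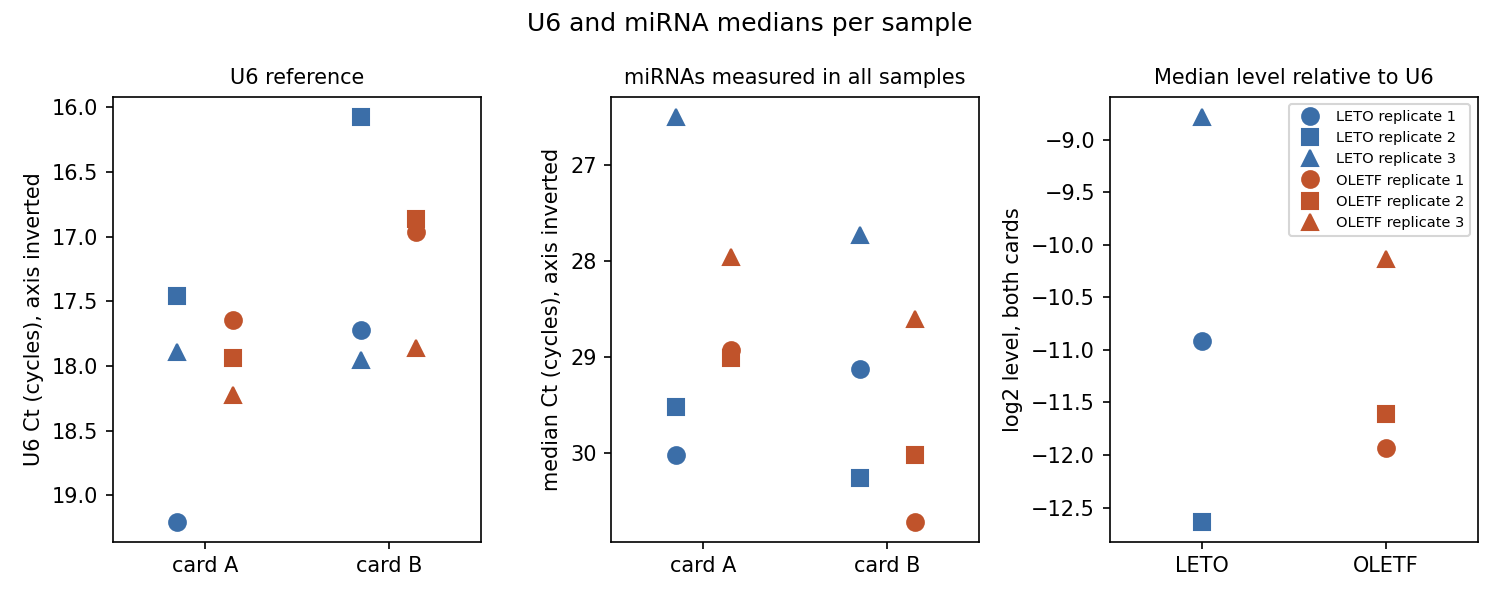
Each point is 1 sample: U6 Ct per card, median Ct of the miRNAs measured in all samples per card (both axes inverted, so that more RNA is higher), and the median log2 level relative to U6 by group. The median level ran from -12.63 to -8.78 within LETO and from -11.94 to -10.13 within OLETF, while LETO replicate 3 had a card A median Ct of 26.5.

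No miRNA differed between OLETF and LETO hearts at an adjusted p under 0.05 (limma, 0 of 193; smallest adjusted p = 0.997). Relative to U6, miR-466d-3p lay lower in OLETF by -3.03 log2 units (SE 1.38) and miR-324-5p by -3.14 (SE 1.54). The value of miR-324-5p came from 2 LETO and 3 OLETF samples. It was 0.10 in the deposited normalized table, which counts an assay with no determined well as 40. miR-466d-3p and miR-324-5p were the 2 assays at an unadjusted limma p under 0.05. They are named after their values were seen, and the ordinary per-assay test gave 1. In OLETF, 156 assays lay lower and 37 higher, and the median change was -0.60 (card A -0.49, card B -1.12; exact permutation p = 0.7 for the medians per sample). The direction of this common shift was set by the reference and by 1 sample: it was 0.37 with the other small RNA controls as reference and 0.38 without LETO replicate 3. The share of assays lower in OLETF was 80.8% with U6, 62.2% with the whole-array median, 67.4% with the per-card median, 51.2% with quantile normalization and 24.9% with the other small RNA controls.

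Replicate 3 of each group had been handled differently in the deposited ratios, so it was also fitted as a batch. With that batch as a block, 1 miRNA passed, miR-466d-3p (-3.03, SE 0.795, limma adjusted p = 0.0297). Relative to U6 its levels were -10.54, -14.05 and -9.17 in LETO replicates 1, 2 and 3, and -16.43, -14.22 and -12.21 in OLETF. The groups thus overlapped, and as limma drew the SE largely from all assays, the call does not rest on the spread of this miRNA alone. Within replicates 1 and 2 alone, 0 of 163 passed. There the mean difference of miR-466d-3p was again -3.03 (SE 1.03, limma adjusted p = 0.597), with a larger SE from 4 samples. It rested on replicate 1 of LETO (-10.54) and OLETF (-16.43), as replicate 2 of each lay close together (-14.05 and -14.22). Array weights gave 30 of 193 at adjusted p under 0.05, all lower in OLETF, among them miR-301b, miR-378, miR-22 and miR-34a. The weights were 3.02, 0.329 and 0.237 for LETO replicates 1, 2 and 3, and 3.25, 3.70 and 0.354 for the OLETF replicates. The LETO side thus rested mostly on replicate 1, and other divisions of the same samples gave up to 169.

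Median references reduced the common shift, to a median change of -0.18 with the whole-array median (card A -0.00011, card B -0.93) and -0.31 with the per-card median (card A -0.28, card B -0.36), and the median SE fell from 1.38 with U6 to 0.514 and 0.464. No miRNA passed with either. With the whole-array median, 17 assays had an unadjusted p under 0.05 (5 higher, 12 lower; limma, smallest adjusted p = 0.384), and with the per-card median 12 did (3 higher, 9 lower; smallest adjusted p = 0.288). The groups did not overlap for 24 of 162 assays with the whole-array median and 22 with the per-card median. Chance gives 10%, or 16.2, on average. As assays vary together between samples, this average does not tell how far such a count strays by chance. No such count was made for other divisions of the samples, so no excess is claimed. Under both, 6 miRNAs lay higher in every OLETF sample: miR-34b-3p, miR-365, miR-193b, miR-218, miR-331-3p and miR-361. Another 6 lay lower: miR-466d-3p, miR-181a, miR-301b, miR-499, miR-29b and miR-29a*. With the per-card median, miR-34b-3p, of a cluster known as a p53 target, differed by 1.40 (SE 0.469), miR-365 by 1.25 (SE 0.452) and miR-193b by 1.07 (SE 0.453). miR-466d-3p differed by -2.27 (SE 0.492), miR-499, encoded within a myosin gene, by -0.90 (SE 0.342), miR-181a by -1.06 (SE 0.351) and miR-29b, which targets collagen mRNAs, by -0.63 (SE 0.356). Their limma adjusted p-values were 0.288 for miR-466d-3p and 0.608 or more for the others.

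**Figure D2:**
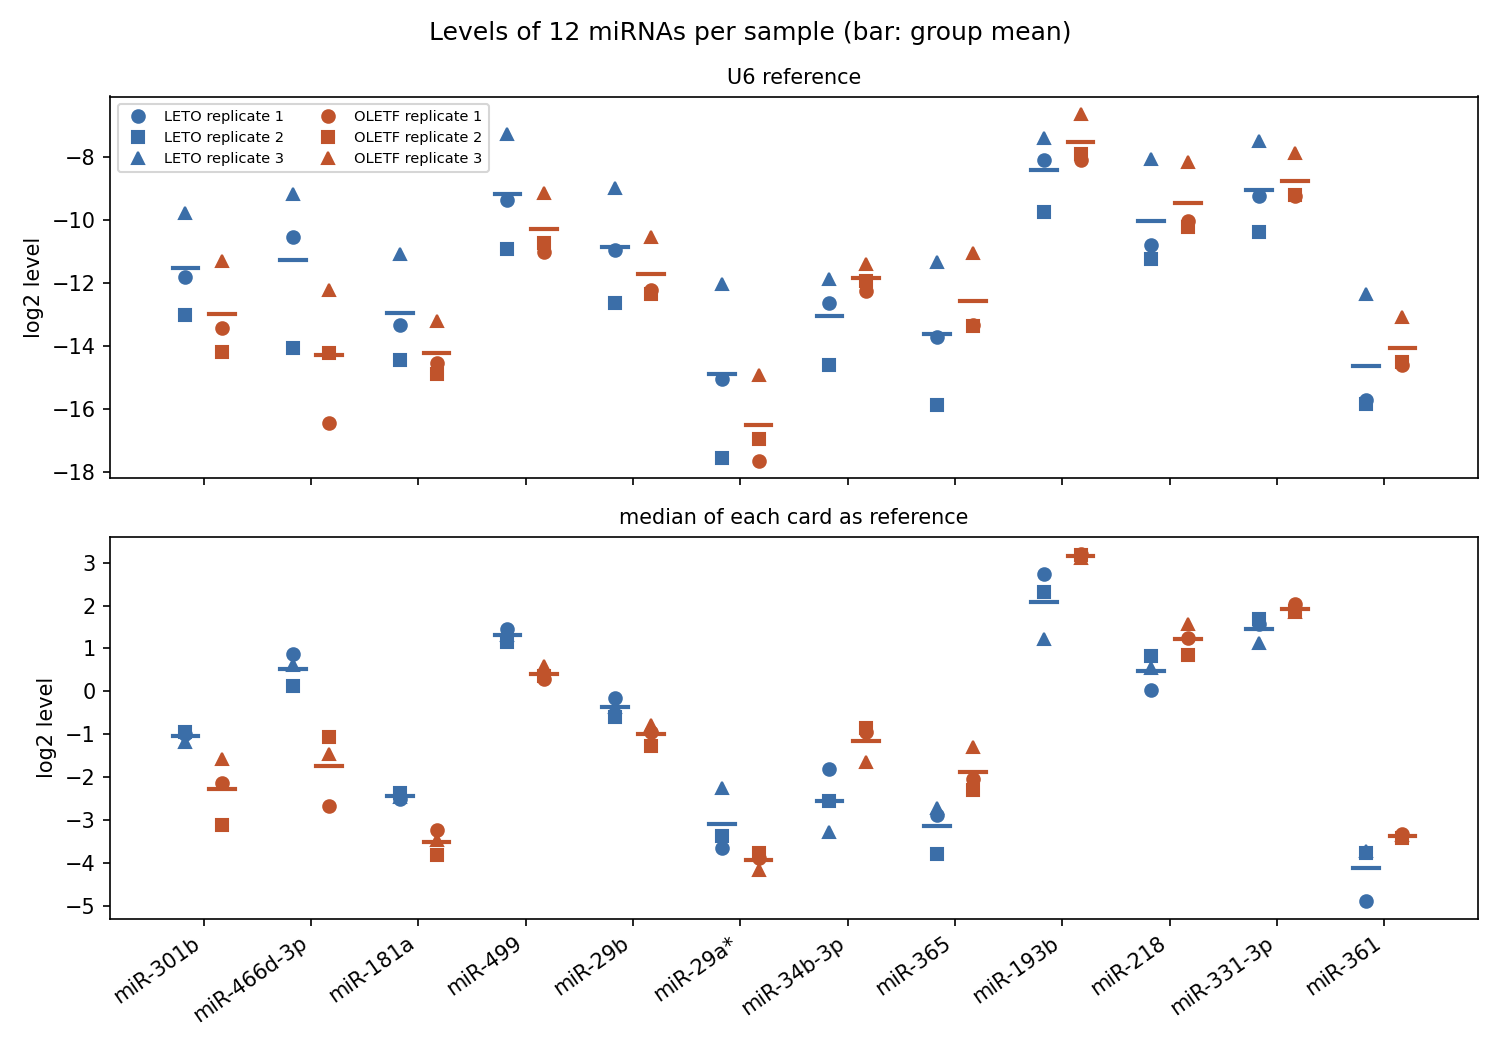
Log2 levels of 12 miRNAs in each sample, relative to U6 (upper panel) and to the median of the card (lower panel); points are samples and bars are group means. miR-301b ran from -13.01 to -9.79 in LETO and from -14.19 to -11.31 in OLETF relative to U6, and from -1.18 to -0.95 and from -3.12 to -1.58 relative to the card median.

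miR-301b, a member of the miR-130/miR-301 family studied in the hearts of these strains, lay lower in OLETF. Relative to U6 its level was -11.54 ± 1.63 in LETO and -12.97 ± 1.49 in OLETF, a difference of -1.44 (SE 1.38, n = 3 each, limma adjusted p = 0.997, exact permutation p = 0.4). Relative to the card median it was -1.04 ± 0.12 and -2.28 ± 0.78, a difference of -1.23 (SE 0.456, limma adjusted p = 0.614), lower in 9 of 9 pairs of samples, with the smallest exact permutation p that 3 against 3 allows, 0.1. With the per-card median the difference was -1.70 within replicates 1 and 2, and -0.39 between the single samples of replicate 3. The authors' deposited table, computed from the same Ct values, gave a ratio of 0.370 for miR-301b. miR-301a differed by -0.99 (SE 1.38) and miR-130a by -0.63 (SE 1.38) relative to U6, and by -0.79 and -0.42 relative to the card median. miR-130b, whose gene neighbours that of miR-301b in the RefSeq gene table, was measured in 3 of 3 LETO and 1 of 3 OLETF samples and was not tested.

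Of the 11 lists tested, 0 shifted against the other miRNAs at an adjusted p under 0.05 (camera in limma), with the preset or the estimated correlation. The miR-130/miR-301 family had 3 of 3 tested members lower, with a median of -0.99 (camera adjusted p = 0.882 with U6 and 0.317 with the per-card median). Of the myomiRs, 8 of 9 tested members lay lower relative to U6, with the rat miR-1 assay at -0.75 and miR-133a at -0.43. Of the fibrosis list 10 of 11 did, with miR-29a at -0.46 and miR-24 at -0.07. With the whole-array median, 4 of 8 myomiRs and 6 of 11 fibrosis members measured in all samples lay higher, and with the per-card median 1 of 8 and 2 of 11. Relative to U6, the let-7 family had 8 of 8 lower (let-7g -0.65, let-7e -0.90) and the miR-30 family 5 of 5 (miR-30c -0.33, miR-30b -0.59), around the common shift of -0.60. With the whole-array median, 4 of 8 let-7 and 3 of 5 miR-30 members lay higher, and with the per-card median 2 of 8 and 0 of 5. Also relative to U6, the miR-17-92 list had 8 of 10 lower (miR-19b -1.11, miR-17 0.08), the miR-15/16 family 4 of 6 (miR-195 -0.60), the miR-23/24/27 clusters 4 of 5 (miR-23a -1.45) and glucose metabolism 17 of 20 (miR-378 -1.11). Of their members measured in all samples, 4 of 9, 3 of 6, 2 of 5 and 10 of 20 lay higher with the whole-array median. With the per-card median, 2 of 9, 2 of 6, 2 of 5 and 6 of 20 did. Adjusted over the list alone, 0 members of any of the 17 lists passed.

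None of the cell type marker lists tested passed. The erythroid list had 2 of 3 tested members higher in OLETF (miR-16 0.40, miR-486 0.27) and a mean 0.79 log2 units above the other miRNAs (camera adjusted p = 0.241; adjusted p = 1.00 with an estimated correlation), and the leukocyte list, with 4 of 9 higher and 5 lower (miR-155 0.69, miR-146a 0.13, miR-150 -0.012, miR-181a -1.26), 0.48 above (camera adjusted p = 0.241; adjusted p = 1.00 with an estimated correlation). These values and the differences that follow are relative to U6. With either median reference, 3 of 3 erythroid and 7 of 9 leukocyte members lay higher, and neither list passed. The camera adjusted p was 0.173 for both with the whole-array median, and 0.317 and 0.388 with the per-card median. miR-486 also stands among the myomiRs and miR-16 in the miR-15/16 family. miR-451, abundant in red cells, was measured in 1 LETO and 0 OLETF samples. Endothelial miR-126-3p differed by -0.06 and miR-126-5p by -0.76, and smooth muscle miR-145 by -0.85 and miR-143 by -0.49. Brain markers had 3 tested members (miR-9 -1.15, miR-128a -1.74 from 2 LETO and 3 OLETF samples, miR-138 0.11; with a Ct limit of 38, which kept all 6 samples, miR-128a differed by 0.073) and liver markers 2 (miR-192 -0.09, miR-194 -0.69), while liver miR-122 and islet miR-375 were measured in 0 samples. Epithelial miR-200c and miR-203 differed by 0.17 and 0.46. Of 54 assays of the Dlk1-Dio3 cluster, 2 were tested, miR-411 (-0.93) and miR-434-3p (-0.51), each from 3 LETO and 2 OLETF samples. Among the members not tested, miR-539 and miR-409-3p were measured in 1 of 3 LETO and 3 of 3 OLETF samples. Others, among them miR-127 and miR-494, were measured in more LETO than OLETF samples.

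A single assay was measured in all samples of 1 group and none of the other. miR-21*, the passenger strand of the fibroblast-enriched miR-21, had a Ct of 34.8, 34.8 and 34.5 in LETO over its determined wells, just under the limit of 35, with 4 of 6 wells determined, and no determined well in OLETF, so no difference is given. No assay was measured in 3 of 3 OLETF and 0 of 3 LETO samples, and with a Ct limit of 32 the count was 0 in both directions.

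The authors' deposited table of ratios listed 32 miRNA wells at 2 or more and 206 at 0.5 or less. Of these, 25 and 119 were undetermined in at least 1 sample, and an undetermined well was in general counted there as 40 cycles. Replicate 3 of each group was the exception on card B, where it entered as the mean of the determined wells of the assay. The highest ratio, 18.0 for miR-539, came with 2 undetermined LETO samples, and the lowest, 0.0160 for let-7c-1*, with 2 undetermined OLETF samples. Across the 193 tested assays, which are not independent replicates, log2 ratios and fitted changes had a Pearson r of 0.722 and the same sign in 94.8%. Over the 162 assays measured in all samples r was 1, as both were computed from the same Ct values.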

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

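The per-card median, the batch of replicate 3, the samples left out under the per-card median or for the group difference in U6 Ct, and the Ct limits and the card A restriction for the deposited ratios were chosen after seeing the data. The count of 0 miRNAs at adjusted p under 0.05 (limma) stayed at 0 in all alternatives except 3. It was 1 with the replicate block, 1 with the batch block, each time miR-466d-3p, and 30 with array weights; the cause was not tested. Counts at an unadjusted p under 0.05 ran from 0 to 62, against 2. Samples with the same replicate number did not deviate together throughout (correlations of deviations -0.088, 0.23 and 0.62 for numbers 1, 2 and 3), so the numbers were not taken as pairs, and the replicate block changed no other call among the lists or miR-301b (-1.44). The number of lists past adjusted p 0.05 was 0 in every alternative run.

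miR-301b stayed lower in OLETF in every alternative. Its unadjusted limma p fell under 0.05 with array weights (-1.91), with the per-card median (-1.23), with the per-card median and the batch block (-1.23), with the per-card median within replicates 1 and 2 (-1.70), and with the per-card median without LETO replicate 3 (-1.30) or OLETF replicate 3 (-1.62); over all alternatives its value ran from -2.27 to -0.56, and the cause was not tested. The median change of all assays was 0.37 with the other small RNA controls as reference, and ran from -1.57 to 0.38 with 1 sample left out, above 0 without LETO replicate 3. With 1 sample left out, the difference in measured assays ran from -41.2 to 3.83, that of U6 Ct from -0.61 to 0.26 on card A and from -0.61 to 0.33 on card B. A Ct limit of 32 left 0 assays measured in 1 group only, as miR-21* lay above it by construction, and raised the r with the deposited ratios to 0.930, where 0 tested assays had an undetermined sample. At the limit of 35, leaving out the 13 tested assays with an undetermined sample raised r to 0.864, so these explain part of the difference.

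With the U6 reference and the settings of the main fit, none of the named miRNAs passed an adjusted p of 0.05 (limma, 2 of 193 assays at an unadjusted p under 0.05, 1 with the ordinary test). Of 56 named miRNAs, miR-301b aside, 6 passed with array weights and 1, miR-466d-3p, with the replicate block. The 6 were mmu-miR-1, miR-324-5p, miR-29a*, miR-378, miR-101b and miR-466d-3p. With the whole-array median, the log2 change took the other sign for miR-24 (0.41), miR-30c (0.16), miR-126-3p (0.42), miR-133a (0.058), miR-150 (0.47), miR-192 (0.40) and miR-29a (0.026). With the other small RNA controls as reference, the log2 change took the other sign for let-7g (0.20), rno-miR-1 (0.11), miR-24 (0.78), miR-27a (0.018), miR-29b (0.016), miR-30b (0.27), miR-30c (0.52), miR-30d (0.20), miR-126-3p (0.79), miR-126-5p (0.093), miR-128a (0.44), miR-130a (0.22), miR-133a (0.42), miR-145 (0.0039), miR-150 (0.84), miR-192 (0.77), miR-194 (0.16), miR-195 (0.25), miR-497 (0.19), miR-143 (0.36), miR-29a (0.39), miR-322 (0.18), miR-378 (0.39) and miR-101b (0.17). With quantile normalization, the log2 change took the other sign for miR-24 (0.33), miR-30b (0.062), miR-30c (0.41), miR-30d (0.034), miR-145 (0.011), miR-150 (0.27), miR-192 (0.35) and miR-194 (0.018). With U6 pooled over both cards, the log2 change took the other sign for miR-24 (0.041), miR-126-3p (0.053), miR-150 (0.10) and miR-192 (0.029). With the deposited normalized table, the log2 change took the other sign for miR-128a (0.073) and miR-324-5p (0.10). With a Ct limit of 38, the log2 change took the other sign for miR-128a (0.073). Without a Ct limit, the log2 change took the other sign for miR-128a (0.073). With array weights, the log2 change took the other sign for miR-138 (-0.68), miR-146a (-0.39), miR-200c (-0.033), miR-486 (-0.36) and miR-17 (-0.49). With the per-card median, the log2 change took the other sign for miR-24 (0.13), miR-126-3p (0.14), miR-150 (0.19) and miR-192 (0.12). With 1 sample left out, the ranges of those that changed sign were let-7g (-1.60 to 0.47), let-7i (-1.79 to 0.25), rno-miR-1 (-1.49 to 0.18), miR-9 (-2.28 to 0.043), miR-16 (-0.13 to 1.03), miR-19a (-2.49 to 0.27), miR-19b (-2.30 to 0.33), miR-24 (-0.79 to 0.75), miR-27a (-1.96 to 0.34), miR-29b (-1.73 to 0.10), miR-30b (-1.52 to 0.41), miR-30c (-1.27 to 0.79), miR-30d (-1.46 to 0.37), miR-126-3p (-0.60 to 0.63), miR-126-5p (-1.72 to 0.52), miR-130a (-1.52 to 0.56), miR-138 (-0.58 to 0.66), miR-145 (-1.94 to 0.28), miR-146a (-0.46 to 0.61), miR-150 (-0.36 to 0.29), miR-192 (-0.78 to 0.72), miR-194 (-1.55 to 0.36), miR-195 (-1.59 to 0.69), miR-200c (-0.40 to 0.69), miR-203 (-0.55 to 1.67), miR-218 (-0.11 to 1.53), miR-301a (-1.90 to 0.32), miR-331-3p (-0.40 to 1.04), miR-361 (-0.040 to 1.71), miR-365 (-0.061 to 2.20), miR-434-3p (-1.42 to 0.23), miR-486 (-0.27 to 0.57), miR-497 (-1.82 to 0.79), miR-143 (-1.61 to 0.87), miR-17 (-0.59 to 0.64), miR-29a (-1.44 to 0.83), miR-322 (-1.58 to 0.20), miR-206 (-2.52 to 0.29) and miR-378 (-2.46 to 0.063). The ranges of those that kept it were let-7e (-1.76 to -0.11), mmu-miR-1 (-1.91 to -0.80), miR-101a (-1.85 to -0.091), miR-133a (-0.87 to -0.19), miR-181a (-2.01 to -0.32), miR-193b (0.20 to 1.38), miR-411 (-1.82 to -0.48), miR-499 (-1.96 to -0.15), let-7a (-1.73 to -0.54), miR-155 (0.20 to 1.24), miR-23a (-1.96 to -1.03), miR-34b-3p (0.41 to 1.77), miR-29a* (-2.95 to -0.19), miR-101b (-2.61 to -0.021), miR-466d-3p (-4.43 to -1.96), miR-128a (-2.63 to -1.19) and miR-324-5p (-3.56 to -2.63). Over the 56 miRNAs, leaving out LETO replicate 2 gave the lowest value for 51 and leaving out LETO replicate 3 the highest for 48. Too few measured samples were left for a value of miR-128a and miR-324-5p without LETO replicate 1 or 3, of miR-411 without OLETF replicate 1 or 3, and of miR-434-3p and miR-206 without OLETF replicate 2 or 3. With the whole-array median, the shift of the list against the other miRNAs took the other sign for miR-17-92 and paralogues (0.043). With the other small RNA controls as reference, the shift of the list against the other miRNAs took the other sign for myomiR (-0.15), fibrosis (-0.096), miR-30 family (-0.069), let-7 family (-0.14), miR-23/24/27 clusters (-0.17) and glucose metabolism (-0.024). With quantile normalization, the shift of the list against the other miRNAs took the other sign for fibrosis (-0.056). With U6 pooled over both cards, the shift of the list against the other miRNAs took the other sign for miR-17-92 and paralogues (0.043). With the deposited normalized table, the shift of the list against the other miRNAs took the other sign for myomiR (-0.042), let-7 family (-0.088) and miR-17-92 and paralogues (0.11). With a Ct limit of 32, the shift of the list against the other miRNAs took the other sign for myomiR (-0.12), fibrosis (-0.095), miR-30 family (-0.0043), let-7 family (-0.16) and glucose metabolism (-0.017). With a Ct limit of 38, the shift of the list against the other miRNAs took the other sign for myomiR (-0.048), let-7 family (-0.094) and miR-17-92 and paralogues (0.10). Without a Ct limit, the shift of the list against the other miRNAs took the other sign for myomiR (-0.042), let-7 family (-0.088) and miR-17-92 and paralogues (0.11). With the per-card median, the shift of the list against the other miRNAs took the other sign for myomiR (-0.13), fibrosis (-0.082), miR-30 family (-0.047), let-7 family (-0.12), miR-23/24/27 clusters (-0.14) and glucose metabolism (-0.0037). With 1 sample left out, the ranges were myomiR (-0.37 to 0.30), fibrosis (-0.20 to 0.21), miR-30 family (-0.011 to 0.16), let-7 family (-0.12 to 0.28), miR-17-92 and paralogues (-0.16 to 0.13), miR-23/24/27 clusters (-0.23 to 0.27) and glucose metabolism (-0.0057 to 0.32), and, for lists that kept their sign, miR-15/16 family (0.055 to 0.41), miR-130/miR-301 family (-0.72 to -0.28), erythroid (0.47 to 1.13) and leukocyte (0.14 to 0.79); leaving out LETO replicate 3 gave the low end for leukocyte and erythroid and LETO replicate 2 the high end. Signals near the limit bound these values: a Ct of 35 leaves 391 assays not tested.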

Other observations

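The tests of LETO replicate 3 and of the cards were chosen after the results were seen; the test of hairpin arms and the counts over other splits of the samples were set out before they were run. For 23 hairpins both the guide and the star strand were tested, among them miR-9, miR-22, miR-27a, miR-29c and miR-133a. With the per-card median, miR-22 and miR-22* differed by -0.92 and -0.76 between OLETF and LETO, miR-9 and miR-9* by -0.94 and -1.19, and miR-29c and miR-29c* by -0.75 and -0.80. In contrast, miR-99b and miR-99b* differed by -0.35 and 0.98, and miR-31 and miR-31* by -0.69 and 0.19. The hypothesis that the arms of a hairpin change together was left open: across the 23 hairpins, which are not independent replicates, Pearson r was 0.19 (permutation p = 0.394) and Spearman's rho 0.25 (permutation p = 0.245), with the same sign in 13.

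miRNA levels relative to U6 were highest in LETO replicate 3, whose median lay 2.99 log2 units above the mean of the other LETO samples. The strain and its diabetes as the whole cause would raise the other LETO samples too. LETO replicate 3 lay 2.45 above the OLETF mean, whereas the mean of LETO replicates 1 and 2 minus that of OLETF was -0.55 (SE 1.02). This comparison drops the highest LETO sample but keeps OLETF replicate 3, the highest of its group, which lowers the difference. With replicate 3 of both groups left out, the median change in OLETF over 163 assays was -0.24, far smaller than 2.45. These values argue against strain and diabetes as the whole cause, though from 2 LETO samples. A smaller contribution of the strain stays open. U6 may be out of step with the other small RNAs: snoRNA135, U87 and Y1 lay earlier in LETO replicate 3 by a mean of -3.59 cycles and the miRNA medians by -2.30, while U6 differed by 0.33. A batch shared by replicate 3 of each group is a candidate explanation too, as OLETF replicate 3 lay 1.64 log2 units above the other OLETF samples, although 1 of 3 samples has to be the highest. Differences between individual animals stay open and were not tested.

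miRNAs of card B lay lower in OLETF than those of card A, by -0.56 log2 units between the card medians (exact permutation p = 0.5). Small RNAs present on both cards showed a like gap: the mean of snoRNA135 and U87 was -0.95 (SE 0.583, exact permutation p = 0.2). This is consistent with a difference between the cards of the same sample, though the permutation p leaves the gap itself within chance, and a real difference of card B miRNAs, many of them star strands, stays open.

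The 6 samples divide into 10 splits of 3 against 3, too few for a share under 0.05. All 10 splits gave at least the real count of 0 miRNAs at adjusted p under 0.05, and the highest other count was 135. That split set LETO replicates 1 and 3 with OLETF replicate 3 against the rest. It also gave the highest counts at an unadjusted p, with U6 and with the per-card median. Such counts point to a structure of the samples. These 3 had the highest median levels relative to U6 (-10.91, -8.78 and -10.13, against -12.63, -11.94 and -11.61). They also had the latest U6 Ct on card B (17.7, 18.0 and 17.9, against 16.1, 17.0 and 16.9). On card A the U6 Ct did not follow the split, with LETO replicate 3 at 17.89 and OLETF replicate 2 at 17.94. With the per-card median, U6 and any shift common to all miRNAs of a card cancel, so neither accounts for the count of 45 there. A difference in level between samples that is unequal among miRNAs would not cancel, and it was not tested. What the split reflects stays open. At an unadjusted p under 0.05, 6 splits gave at least the real 2 (highest other 145) with U6, and 3 gave at least the real 12 (highest other 45) with the per-card median. With array weights, 8 of 10 splits gave at least the real 30, and the highest other count was 169. For the lists, all 10 gave at least the real 0, and the highest other was 1.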
